A study of Caenorhabditis elegans with 2 samples.

How the data were processed

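Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on whole Caenorhabditis elegans of strain OP658, per the labels. The strain carries a transgene that expresses the protein of gene F10E7.11 with a C-terminal GFP and FLAG tag, in an unc-119 mutant background. The worms were mixed-sex young adults collected 63 hours after synchronisation of starved L1 larvae, chromatin was sheared by sonication, and the immunoprecipitation used an anti-GFP antibody, per the labels. The antibody field of the labels names F10E7.11 itself, so the anti-GFP antibody is taken from the description field. The samples form 1 group of 2 biological replicates, numbered 1 and 2 as in the labels, with no second condition. The authors used a control library for peak calling, per the deposited file lists; control data were not analysed here.

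The values are those of the authors' deposited peak lists. For assemblies ce10 and ce11, the lists hold candidate regions of each replicate and of the pooled replicates, which were meant as input for the irreproducible discovery rate (IDR) procedure, and a shorter list of pooled peaks past an IDR threshold. Each region has a signal value given by the authors' peak caller, a −log10 of a q-value in the deposited lists, and a summit. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The signal values are the authors' own, are on a different scale in each list, and were used to rank or describe regions within a list. Read depth is unknown from these files, so no value here carries a counting error of reads; intervals on shares of peaks are exact Clopper-Pearson 95% intervals and cover the number of peaks only. The candidate lists include background regions by design: the q-value was under 0.05 for 996 of 18286 pooled regions in ce11.

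Annotation and sequence came from assembly WBcel235, which is ce11, with Ensembl release 115 genes, and were used with the ce11 lists alone. Lists in ce10 entered only as counts, ranks, overlaps among themselves and counts per chromosome, and no coordinate was converted between assemblies. A promoter was the window from 500 bp upstream to 100 bp downstream of a protein-coding 5′ end. Every summit was given 1 class, in the order promoter, 5′ UTR, coding exon, 3′ UTR, noncoding exon, intron and intergenic.

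Shares of summits in a class or near a gene type were compared with 10000 circular shifts of the summits along each chromosome. These shift tests were two-sided, with a smallest possible p of 0.0002, and one-sided, with a smallest possible p of 0.0001, for the overlap of replicates. Reciprocal overlap was tested with 1000 shifts. Correlations across regions used 100000 permutations, or 1000 over all pooled candidate regions; regions are not independent replicates. Chromosome counts were compared with exact binomial tests, and gene lists with two-sided Fisher's exact tests against all 19973 protein-coding genes on the 6 nuclear chromosomes. Words of 6 bases, counted on both strands as present or absent, were compared by Fisher's exact test between 100 bp windows at the summits and windows of the same length centred 300 bp to either side. Adjusted p-values are Benjamini-Hochberg values within each family of tests. The computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

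The gene lists, the 12 sequence motifs, the tests, and the alternatives not described as added were fixed before the data were examined. Gene lists were defined by gene symbols, so their members share a naming class and were not curated one by one; lists with at least 5 members were tested. The genes named are F10E7.11 and unc-119; genes at the 25 strongest IDR peaks with a summit in a protein-coding promoter and in a candidate region of both replicates; up to 4 bound members of each list past the threshold and of 4 lists that were not; noncoding RNA genes at the 10 strongest IDR peaks; and the 10 words of lowest p. Genes named outside this rule are said to be chosen after their values were seen.

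The shift, list and word tests were tested on simulated data, with 20 sets of 575 random positions with nothing planted and 20 sets with planted signal. In the planted sets 100 promoters, 12 genes of the ribosomal protein list, 15 snoRNA genes and 40 windows with a word were added. The promoter share, the snoRNA share, the list and the word were called in 20 of 20 planted sets and in 0 of 20 sets with nothing planted. In the planted sets, another gene list passed in 2 of 20 and another word in 4 of 20. The simulation was written after the tests had first been run on the deposited lists, and the planted word was ACGCAG. Random positions lack the difference in G+C content between real summits and flanks. The sets with nothing planted thus do not cover false calls that base composition could give.

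Alternatives included another promoter window, the 288 strongest IDR peaks by signal value, other backgrounds and distances, and the ce10 lists. A replicate was left out by taking, from the candidate list of the other replicate alone, as many of the strongest regions as there were IDR peaks. Alternatives without peaks near small RNA genes, with windows matched in G+C content, with regions of the common width and with counts of regions at the tagged gene were chosen after seeing the data.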

Results

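Binding of the F10E7.11 protein was mapped by ChIP-seq against a GFP tag in whole young adult C. elegans, with 2 biological replicates of 1 strain. The labels state no comparison group, so the questions are where the protein was detected and how far the replicates match. The ce11 lists held 18116 candidate regions for replicate 1, 25275 for replicate 2 and 18286 for the pooled replicates. The IDR list held 575 peaks, which were the 575 pooled regions of highest signal value. In ce10 the IDR list held 642 peaks. Values below are for ce11 unless ce10 is named. Most regions of the IDR list were 436 bp wide, and 28 had another width, of which 19 were among the 30 strongest peaks. A pair of peaks shared 1 interval with different summits. Read depth is unknown from these files.

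Most of the 10 strongest IDR peaks lay at small noncoding RNA genes or at protein-coding genes, and 1 lay in intergenic sequence with no gene within 250 bp. The strongest, on chromosome II from 5661571 to 5662028 in ce11, had its summit in a coding exon of mdt-26 and a pooled signal value of 655. The next, on chromosome V from 12303522 to 12303725, lay in a noncoding exon at the snoRNA genes C51F7.3 and C51F7.4, with a signal value of 638. The peak on chromosome V from 8500434 to 8500650 lay in an intron of pxn-1 next to the snoRNA gene ZK994.7, with a signal value of 633. Among the 10 strongest peaks were also those at the snoRNA gene T03F7.8 with the noncoding gene T03F7.14 (signal value 495), at the spliced leader gene sls-2.4 with R12E2.18 (487), at wwp-1 with the noncoding gene Y65B4BR.10 (472) and at rpr-1 (459). The intergenic peak spanned chromosome X from 11094131 to 11094345, with a signal value of 489.7. Among the 30 strongest peaks, other intergenic peaks on X with no gene within 250 bp reached 431, 391, 374, 347 and 338. The protein-coding genes mdt-26 and pxn-1 were chosen after their values were seen. Small nucleolar RNAs guide the modification of other RNAs, spliced leader RNAs are joined to the front of messenger RNAs, and rpr-1 encodes the RNA of RNase P, which processes tRNA precursors.

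The strongest regions of the replicates, listed separately, overlapped far more than shifted regions. Of the 575 strongest regions of each replicate, 266 had summits within 100 bp of each other, or 46.3%, against a mean of 0.124% after shifting (one-sided circular-shift permutation p = 0.0001, the smallest possible). The summits of 575 of 575 IDR peaks lay in a candidate region of replicate 1 and 573 of 575 in one of replicate 2. The IDR peaks were the 575 pooled regions of highest signal value, and the pooled list draws on both replicates. This coverage is thus not a separate measure of how far they match. It was not complete in replicate 2, so the list does not show that each peak was consistent between them. The peak at mdt-26 ranked 2 in replicate 1 and 1 in replicate 2, and that at ZK994.7 ranked 3 and 2.

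The signal values of the replicates were positively correlated across peaks. Across the 573 IDR peaks with a region in both replicates, the signal values of the replicates had a Spearman correlation of 0.273 (permutation p = 1e-05, the smallest possible). The Pearson correlation of their log2 values was 0.44. These peaks were selected for a high pooled signal value, which narrows the range. The Spearman correlation was 0.399 over all 9130 pooled candidate regions with a region in both replicates, and 0.362 in ce10. The pooled signal value followed replicate 1 with a Spearman correlation of 0.858 and replicate 2 with 0.600. The median rank of the IDR peaks was 288 in replicate 1 and 371 in replicate 2, and the lowest rank in replicate 2 was 23716. Regions within one experiment are not independent replicates, and the q-values of the lists do not enter these ranks.

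Summits at tRNA, snoRNA and snRNA genes were far more frequent than at shifted positions. Transfer RNA genes had 85 of 575 summits within 250 bp, or 14.8% (95% interval 11.98 to 17.95), against 0.337% after shifting. The snoRNA genes had 50 summits, or 8.70% (6.52 to 11.3), against 0.223%, and snRNA genes had 15, or 2.61% (1.47 to 4.27), against 0.0723%. Each difference had a two-sided permutation p of 0.0002, the smallest possible, and an adjusted p of 0.000333 over 5 gene types. In gene numbers, a summit lay at 95 of 612 tRNA genes, 50 of 346 snoRNA genes and 13 of 129 snRNA genes. The miRNA genes had 5 summits (0.870%, against 0.141%, permutation adjusted p = 0.0060), but did not pass among the 288 strongest peaks (0.694%, permutation p = 0.130). The rRNA genes had 0 of 575 summits, against 0.0176% after shifting, with an upper limit of 0.639%. With 20 such genes and so low a background, this does not show an absence of peaks.

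Both replicates alone gave the same direction at these genes. Among as many of the strongest regions of replicate 1, 13.6% of summits lay at tRNA genes and 8.17% at snoRNA genes. In replicate 2 the shares were 9.91% and 6.96%. Among the 288 strongest IDR peaks, snoRNA genes held 13.2%. Among the IDR peaks of the rule, the tRNA gene WBGene00014499 lay at the same peak as the chemosensory receptor gene srh-269. The tRNA gene WBGene00022947 lay at the peak of sec-15, and the snoRNA gene D1046.6 at that of cfim-2. The snoRNA gene C41C4.11 lay at the peak of chst-1 and C41C4.9, and F39B2.14 at that of tmem-107 and rps-26. The RNA genes at these peaks were chosen after their values were seen.

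**Figure D1:**
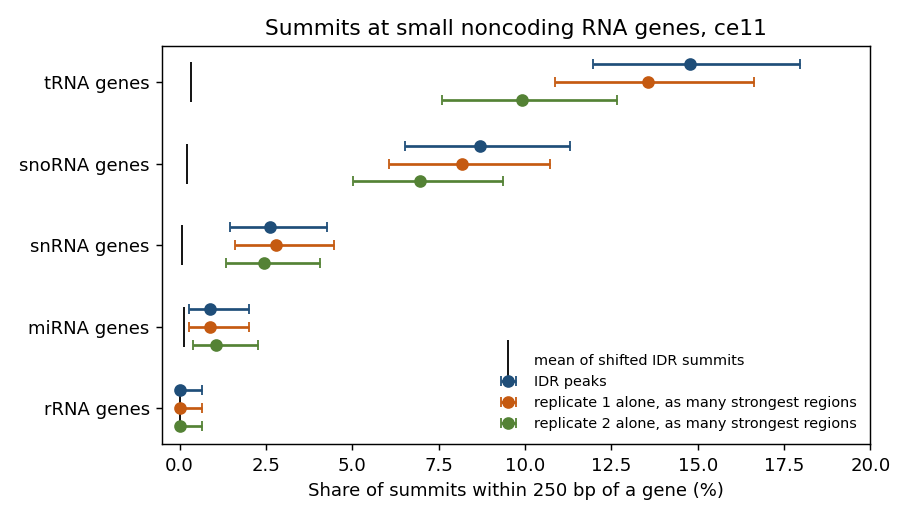
Share of summits, in percent, within 250 bp of genes of 5 noncoding types, for the 575 IDR peaks and for as many of the strongest regions of each replicate alone. Points are shares, bars exact 95% intervals and black ticks the mean of shifted IDR summits; tRNA genes stand at 14.8% against 0.337%.

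Promoters of protein-coding genes held 174 of 575 summits, or 30.3% (95% interval 26.5 to 34.2), against 14.01% after shifting (two-sided permutation p = 0.0002). Noncoding exons held 14.6% against 2.91%, and 3′ UTRs 6.26% against 2.81%. Coding exons held 11.1% against 21.9% and introns 11.5% against 31.9%, both below the shifted summits. Each of these had an adjusted p of 0.00028 over 7 classes. Without replicate 1 coding exons held 17.04% against 21.99% (permutation adjusted p = 0.0067). Intergenic sequence held 25.7% against 25.8%, and 5′ UTRs 0.522% against 0.694%, with an adjusted p of 1 for each. The share in 3′ UTRs did not pass among the 288 strongest peaks, where it was 4.51% (permutation adjusted p = 0.185). Without the peaks near small RNA genes, an alternative chosen after seeing the data, noncoding exons held 24 of 420 summits, or 5.71% against 2.89% (permutation adjusted p = 0.0059), so most of their excess lay at those genes.

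**Figure D2:**
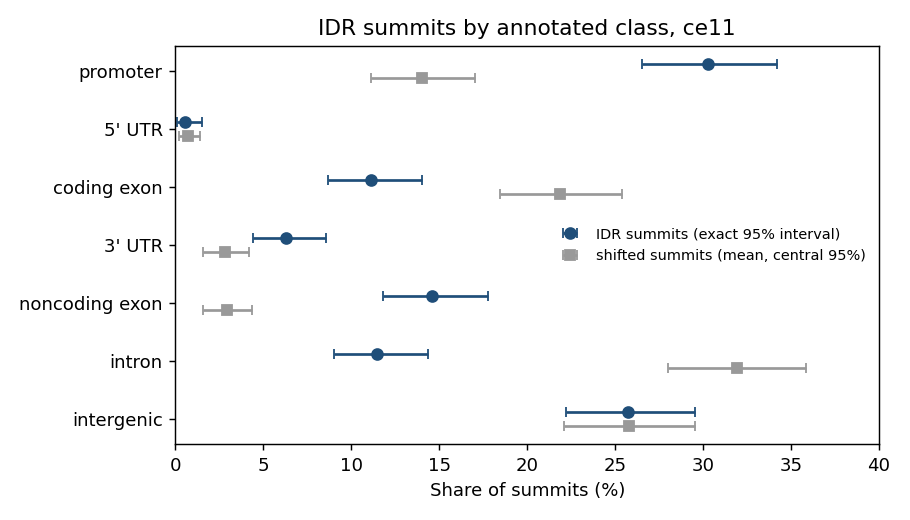
Share of the 575 IDR summits in each annotated class of ce11, in percent, as blue circles with exact 95% intervals, beside shifted summits as grey squares with the central 95% of 10000 shifts. Promoters lie at 30.3% against 14.01%, and introns at 11.5% against 31.9%.

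The pooled candidate regions that were not IDR peaks had 3446 of 17711 summits in promoters, or 19.5%, below the 30.3% of the IDR peaks (odds ratio 1.80, Fisher's exact p = 1.41e-09). The 421 of them with a q-value under 0.05 had 146 summits in promoters, or 34.7%.

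Among promoters, the strongest peaks lay at tasp-1, rpl-3, wwp-1, kin-14 and kel-3. The peak at tasp-1 spanned chromosome III from 10759029 to 10759464, with its summit 60 bp from the 5′ end; its signal values were 553 pooled, 402 in replicate 1 and 145 in replicate 2. The peak at rpl-3, a protein of the large ribosomal subunit, spanned chromosome III from 3867465 to 3867680, with signal values of 518, 367 and 155. The peak at wwp-1, a ubiquitin ligase, spanned chromosome I from 536774 to 536986, with a pooled signal value of 472. That at kin-14 reached 442, that at kel-3 389 and that at ego-1, an RNA-dependent RNA polymerase of the germ line, 382. A peak between the divergent genes F44E5.4 and F44E5.5 reached 378 and ranked 17 in replicate 1 and 62 in replicate 2.

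The other promoter peaks among the 25 strongest lay at rpl-15 with K11H12.8, Y22D7AL.10, W04C9.4, rpi-2, dnj-13, Y55F3AR.2 with cct-8, Y17G9B.5 with rpl-20, fubl-1, adss-1, F56G4.6 with wbp-4, cfim-2, cox-5A, rpl-35, rpac-19, tmem-107 with rps-26, chst-1 with C41C4.9, cdc-48.1 and sec-61.G. Their pooled signal values ran from 342 at rpl-15 to 264 at sec-61.G. Replicate ranks differed most at the peak of tmem-107 and rps-26, which ranked 46 in replicate 1 and 513 in replicate 2.

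Genes of cytosolic ribosomal proteins had promoter peaks more often than other genes. Of 81 such genes, 11 had an IDR summit in the promoter, or 13.6%, against 0.986% of all 19973 protein-coding genes (odds ratio 16.6, Fisher's exact adjusted p = 1.68e-08 over 39 lists). They included rpl-3 (signal value 518), rpl-15 (342), rpl-20 (314) and rpl-35 (284). The list passed under each alternative, with odds ratios as low as 6.94 when genes with a pooled candidate region at the promoter were the background. The peak at 1 of the 11 genes, rps-26, also lay within 250 bp of a small RNA gene. Control data were not analysed here, so recovery of these promoters in any immunoprecipitation was not tested.

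Chaperonin and heat-shock protein genes had promoter peaks at 4 of 60 members, dnj-13 (320), cct-8 (320), hsp-1 (241) and hsp-90 (203), with an odds ratio of 7.30 and an adjusted p of 0.0378. The call was lost without replicate 1, with 3 of 60 members and an odds ratio of 5.49 (Fisher's exact adjusted p = 0.195). It was also lost against the background of genes with a candidate region (Fisher's exact adjusted p = 0.413) and with the nearest gene alone (0.332). Chemosensory receptor genes, a family of G protein-coupled receptors, had a peak at 1 of 1365 members, srh-269 (signal value 262), an odds ratio of 0.0689 with a Fisher's exact adjusted p of 0.000469. That difference did not pass among the 288 strongest peaks (Fisher's exact adjusted p = 0.0624) or against genes with a candidate region (0.632).

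Lists that did not pass were led by rab and vesicle transport genes, with 4 of 72 (sec-61.G, sec-15, arf-1 and rab-7; Fisher's exact adjusted p = 0.0546), and chromatin regulators, with 4 of 85 (lin-53, lin-54, set-16 and set-2; adjusted p = 0.0779). DNA replication and cell cycle genes had 3 of 53 (cdc-48.1, pcn-1 and cdk-7; Fisher's exact adjusted p = 0.100), and RNA polymerase and Mediator genes 3 of 64 (rpac-19, rpb-11 and taf-9; adjusted p = 0.134). DNA replication and cell cycle genes passed without replicate 2, with 4 of 53 (Fisher's exact adjusted p = 0.0184), and chromatin regulators with the wider promoter window, with 6 of 85 (0.0134). Among tissue and germ line lists, none of which passed, promoter peaks lay at 0 of 40 meiotic, 0 of 42 P granule, 0 of 34 oocyte, 0 of 94 sperm, 0 of 44 intestine, 0 of 42 muscle and 0 of 13 gonad sheath genes. Epidermis markers had 1 of 79, synapse genes 1 of 40 and pharynx markers 3 of 86. Against 0.986% of all genes, the pharynx list lay above the background without passing (Fisher's exact adjusted p = 0.231), and lists of this size are too small for an absence of peaks to be told from chance.

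Promoters shared by opposite genes held more of the promoter summits than after shifting. Of 174 promoter summits, 29 lay between opposite 5′ ends within 1000 bp of each other, or 16.7%, against 7.37% (two-sided permutation p = 0.0078). Among the 288 strongest peaks the share was 25.8%.

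Peaks were unevenly spread over the chromosomes. Chromosome III held 105 of 575 peaks against 79.0 expected from its length (adjusted p = 0.0072, exact binomial test), chromosome I 107 against 86.4 (adjusted p = 0.0389) and chromosome V 81 against 120.0 (adjusted p = 0.000228). The share of chromosome I, 18.6%, fell to 16.3% among the 288 strongest peaks and did not pass (exact adjusted p = 0.747). It was 18.1% both without replicate 2 (exact adjusted p = 0.0705) and on the ce10 list (0.0712), and did not pass in either. The X chromosome held 105 peaks against 101.6 (exact adjusted p = 0.702), chromosome II 92 against 87.6 and chromosome IV 85 against 100.3. Without replicate 2, chromosome IV held fewer peaks than expected, with 75 (exact adjusted p = 0.00999). With protein-coding genes as the expectation, X held more peaks than the 78.6 expected (exact adjusted p = 0.0039). The middle 50% of the autosomes held 278 of 470 autosomal peaks, or 59.1% (exact binomial p = 8.46e-05), but 55.7% was expected from the positions of protein-coding genes (p = 0.137).

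The 10 words of lowest p were either mainly of G and C and more frequent at the summits, as ACGCAG was, or of A and T alone and less frequent. The word ACGCAG, counted with its reverse complement CTGCGT, lay in 65 of 575 summit windows, or 11.3%, and in 18 of 1150 flanking windows, or 1.57% (odds ratio 8.02, Fisher's exact adjusted p = 8.78e-15 over 2080 words). GACGCA had an odds ratio of 6.79, CACTCG 6.77, CTGCGC 8.37, GCAGAC 7.25, CCTGCG 8.29 and CGAGAG 3.75. Several words share bases, as GACGCA and GCAGAC do with ACGCAG, so they are not independent of each other. AAAAAT lay in 24.3% of summit windows and 45.7% of flanks (odds ratio 0.382), AAAATT had an odds ratio of 0.442 and AAAAAA 0.446. Without replicate 1 the odds ratio was 3.28 for ACGCAG, 3.73 for GACGCA, 3.602 for CACTCG, 4.85 for CTGCGC and 2.72 for GCAGAC, and without replicate 2 it was 3.96 for CACTCG. Against the summits of other candidate regions, the odds ratio was 3.36 for ACGCAG, 2.60 for GACGCA, 3.40 for CACTCG and 3.41 for CTGCGC. There it was 2.33 for GCAGAC, 3.81 for CCTGCG, 2.94 for CGAGAG, 0.631 for AAAAAT, 0.732 for AAAATT and 0.627 for AAAAAA. With windows of 200 bp, the odds ratios of the more frequent words ran from 2.76 for CACTCG to 6.49 for CCTGCG, with 4.97 for ACGCAG. Each of these passed. In all, 276 words were more and 146 less frequent, and the windows held 45.6% ± 9.60 G+C (SD, 575 windows) at summits and 36.4% ± 8.80 in flanks (SD, 1150 windows).

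Against genome windows of the same G+C content, an alternative chosen after seeing the data, ACGCAG had an odds ratio of 3.14 (Fisher's exact adjusted p = 1.51e-09). Those of GACGCA (2.73), CACTCG (3.23), CTGCGC (2.98), GCAGAC (2.25), CCTGCG (3.0035) and CGAGAG (2.67) were also lower and passed, and the differences of AAAAAT, AAAATT and AAAAAA did not pass. Of the 12 motifs, adjusted over the list alone, the GAGA repeat (odds ratio 2.46), SP1 box (3.91) and E-box (2.43) were more frequent at summits. The GATA element (0.529), TATA box (0.490), T block (0.428) and CHR element (0.478) were less frequent. With matched G+C content, the GAGA repeat (2.12) and SP1 box (1.67) passed and the other motifs did not. The SP1 box, the E-box and the CHR element did not pass without replicate 1, with odds ratios of 1.78, 1.95 and 0.756 (Fisher's exact adjusted p = 0.0578 for each). Among the 288 strongest peaks the E-box kept its odds ratio of 2.43 and the TATA box had 0.588, but with fewer peaks neither passed (Fisher's exact adjusted p = 0.0777 for each). Against the summits of other candidate regions, the GATA element (odds ratio 0.778, Fisher's exact adjusted p = 0.0889) and the TATA box (odds ratio 0.846, adjusted p = 0.564) did not pass. The SP1 box passed in both of these settings, but its odds ratio moved to 9.53 among the 288 strongest peaks and to 2.26 against other candidate summits.

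**Figure D3:**
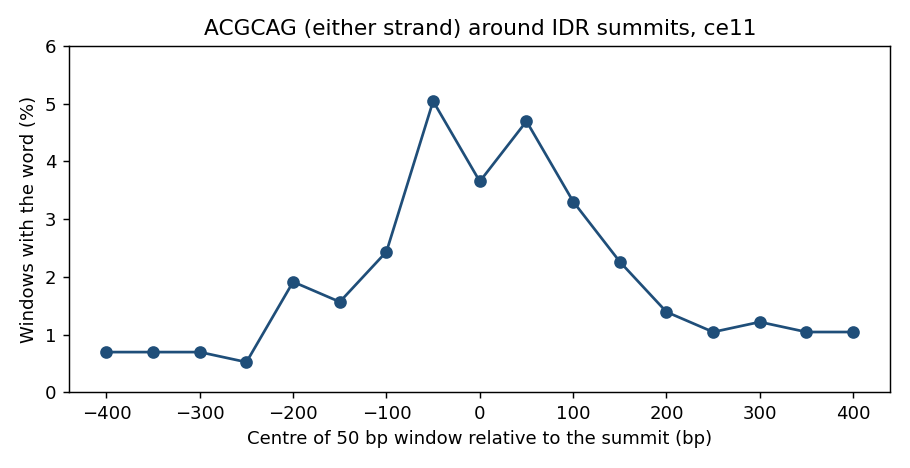
Share of windows of 50 bp, in percent, that hold ACGCAG or CTGCGT, by the distance of the window centre from the 575 IDR summits in bp. The share was 5.04% at 50 bp before and 4.70% at 50 bp after the summit, and 0.696% at 400 bp before it. In the window centred on the summit it was lower than at these nearest offsets, at 3.65%.

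The gene F10E7.11 itself, on chromosome II from 7120517 to 7122892, had no IDR peak within the gene, but 16 pooled candidate regions lay within 20 kb of its centre, against a median of 7 around protein-coding genes. Their summed signal value of 1599 was reached by 1.88% of 19973 such windows. The tag is carried by a transgene, and extra copies of the tagged gene would raise coverage there. The peak lists cannot tell this from binding. The pooled region at F10E7.11 itself had a signal value of 68.9, below the median of 71.9 of the pooled list. Most of the sum thus came from regions around the gene. The 3 IDR peaks in the window lay at rpl-33, at F10E7.6 and between genes, with signal values of 186, 219 and 166. The neighbours rpl-33 and F10E7.6 were chosen after their values were seen. Within 10 kb the window was not exceptional, as 24.0% of windows reached its sum, and with replicate 1 alone 5.11% did. At unc-119, the gene mutated in the strain, on chromosome III from 10902641 to 10908935, 6 pooled regions and 0 IDR peaks lay within 20 kb, and 54.8% of windows reached its sum.

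**Figure D4:**
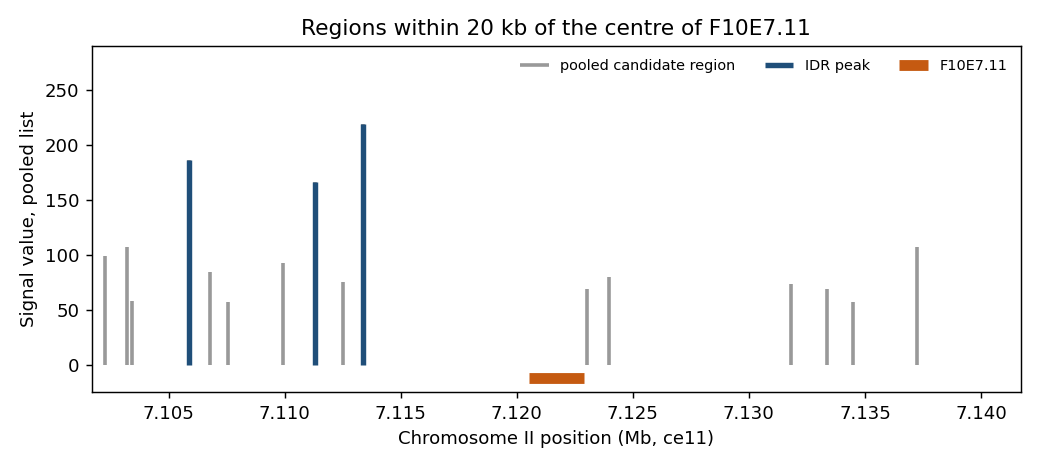
Pooled candidate regions (grey) and IDR peaks (blue) within 20 kb of the centre of F10E7.11 (orange bar) on chromosome II of ce11, drawn at their summits, with the signal value of the pooled list on the vertical axis. The 3 IDR peaks, at 166 to 219, lie to the left of the gene.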

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

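The copy-number tests, the bound on G+C content as the whole cause and the tests of the assemblies were chosen after the result was seen. Outside the IDR list, 421 pooled candidate regions had a q-value under 0.05, a signal outside the peaks that the comparisons above are about. Of these, 40 had a summit at a tRNA gene (9.50% against 0.298% after shifting, permutation p = 0.0002), 10 at a snoRNA gene and 146 in a protein-coding promoter (34.7% against 14.2%, permutation p = 0.0002).

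The summits at tRNA, snoRNA and snRNA genes, 26.1% of all IDR summits, were set against technical explanations. Positions with the same G+C content lay at these genes in 0.887% of cases, which argues against base composition. Reads shared between near-identical copies are argued against for snoRNA genes, since 43 of 50 with a summit, or 86% (95% interval 73.3 to 94.2), held no repeated 32-base word within 200 bp. For tRNA and snRNA genes this stays open, since nearly all hold repeated words: 0 of 95 tRNA genes with a summit and 16 of 517 without were free of them, and 1 of 13 (7.69%) and 13 of 116 snRNA genes. Most words there were still unique, with a median share of 87.6% at tRNA genes with a summit and 87.7% without. At snRNA genes it was 87.2% and 78.5%. These shares cannot decide the question, since dropped reads that map to several places could also raise the share at summits. A comparison of mean shares was replaced by the count of genes free of repeated words after both were seen. Recovery of these loci in any immunoprecipitation stays open too, since control data were not analysed here, and no biological explanation was tested with 1 group.

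The word ACGCAG was tested against base composition and against the sequence of small RNA genes. With windows of the same G+C content, its odds ratio fell from 8.02 to 3.14, so composition may account for part of it. The fall was past the halving taken as the mark of composition. That mark was set before this comparison was run, but after the word had been picked from these data. As the whole cause it is argued against by the lower 95% bound of 2.35. Without summits near small RNA genes the odds ratio was 9.95, so its excess does not rest on those genes. Other properties of the bound sequences stay open, and no biological explanation was tested.

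Replicate 1 had other signal values in ce10 than in ce11, with a median ratio of 1.38 over the 1000 strongest ranks. The pooled list, which draws on both replicates, had a median ratio of 1.29. The IDR list held 642 peaks in ce10 and 575 in ce11. A change of assembly is argued against by replicate 2, whose ratio was 1. The ratio of replicate 1 was nearly even over ranks (90th over 10th percentile 1.02), as a common factor on all values would give. Rescaling alone is argued against, since the common width was 440 bp in ce10 and 436 bp in ce11, with 16540 and 18116 regions, while replicate 2 kept 444 bp; another set of reads or other peak caller settings were not tested.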

How the results depend on the processing

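Alternatives without peaks near small RNA genes, with matched G+C content, with regions of the common width and with counts of regions at the tagged gene were chosen after seeing the data. Of all alternatives to the results above, 308 of 357 kept the direction and side of the threshold, or a count within 1.5 times. The promoter share, the calls of the classes other than 3′ UTR (coding exons at 17.04% without replicate 1), the overlap of the strongest regions and the correlation of the replicates, the direction and call of the shares at tRNA, snoRNA and snRNA genes and the divergent promoters held under every alternative run. Where not stated otherwise, the cause of a change was not tested.

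The 288 strongest peaks, fewer by construction, gave 4.51% in 3′ UTRs, 0.694% at miRNA genes, 0 lists below the background, and 168 words more and 96 less frequent. With protein-coding genes as the expectation, the X share of 18.3% passed and the middle share of 59.1% did not. The wider promoter window gave 6 lists above the background in place of 2, adding translation factors, the respiratory chain, autophagy genes and chromatin regulators; the background of genes with a candidate region gave 1 above and 0 below, and the nearest gene alone gave 1. Without 1 replicate, 1 to 4 lists were above the background, with the respiratory chain and DNA replication added without replicate 2, 172 to 214 words were more frequent, and 2.53% to 5.11% of windows reached the sum at F10E7.11; within 10 kb 24.0% did. Candidate summits outside the IDR list as background gave 163 words more and 57 less frequent. Without peaks near small RNA genes the counts were 120 and 59, and with matched G+C content 121 and 46. Matched G+C content also turned the odds ratios of AAAAAA (1.07), AAAATT (1.105), the TATA box (1.31) and the T block (1.11) above 1, none past the threshold. Depth is unknown from these files, so its limit on weaker peaks could not be stated.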

Other observations

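The tests of the X genes, the SL2 genes, the summit position and the word by kind of summit were chosen after the result was seen; the host gene test was not. Within the tRNA genes, those on X had an IDR summit more often, 57 of 276 or 20.7%, than those on autosomes, 38 of 336 or 11.3% (odds ratio 2.04, Fisher's exact adjusted p = 0.0033 over 6 tests). Within the snRNA genes, 6 of 18 genes of the SL2 spliced leader (sls-2), or 33.3%, had a summit, against 7 of 111 others (odds ratio 7.43, Fisher's exact adjusted p = 0.0045). Neighbouring genes can share a summit, so genes are not fully independent in these tests. The snRNA genes with a summit also held more unique sequence, with a median of 87.2% against 78.5% without. Unique sequence was not compared between sls-2 and other snRNA genes, so a part of it in the sls-2 difference stays open.

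A hypothesis was that summits lie upstream of snoRNA and snRNA genes but not of tRNA genes, whose promoter elements lie inside the gene. Of snoRNA and snRNA genes with a summit, 63.5% had it upstream, against 34.7% of tRNA genes (Fisher's exact adjusted p = 0.0017). By gene type, the snoRNA genes had 38 of 50 or 76.0% upstream (Fisher's exact adjusted p = 2.25e-05), and the median over all 50 was 36 bp upstream of the 5′ end. The snRNA genes had 2 of 13 or 15.4% upstream and 9 downstream (Fisher's exact adjusted p = 0.215). At snRNA genes the difference thus ran the other way and did not pass. A higher upstream share than at tRNA genes was therefore seen at snoRNA genes alone. The tests were chosen after the result was seen, on the same summits, so they are no separate test of the hypothesis. Its part on tRNA genes was not tested by itself: 33 had the summit upstream, 42 within and 20 downstream.

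A further hypothesis was that snoRNA genes with a summit lie less often inside a protein-coding gene on the same strand. The share was 42% with a summit and 54.7% without (Fisher's exact adjusted p = 0.150), which did not pass.

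The share of summits with the word ACGCAG was compared between kinds of summit. The word lay in 14.1% of summits at tRNA genes, 8% at snoRNA genes, 14.2% at promoters without such genes and 10% elsewhere, and in 0 of 15 summits at snRNA genes, with no kind past the threshold (Fisher's exact adjusted p of at least 0.495). The 8-base word of lowest p was GACGCAGA, which contains it, in 28 of 575 summit windows and 5 of 1150 flanks. The words next in p do not contain it. They were CTGAGCTA, in 20 summit windows and 1 flank, and GCTCTACC, in 17 and 0. Whether these words lie at small RNA genes was not tested.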
